A study of Mus musculus with 2 samples.

How the data were processed

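Total RNA from sorted splenic cells of infected C57BL/6 and Ch25h-/- mice was extracted with TRIzol and made into libraries with the KAPA RNA HyperPrep kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, GSNAP 2018-07-04, featureCounts, Subread 1.5.2 and edgeR 3.26.8, and the builds GRCm38 and mm10. The deposited table holds whole read counts per gene, which were used as given, and the notes do not state the strand setting, the treatment of reads that match several places, or how many mice went into each library. Only the 2 columns of the table were used, 1 per genotype, and both were analysed.

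The table lists 30538 genes, of which 14034 had 0 counts in both libraries. Of the gene IDs, 30126 are in GENCODE M21 (GRCm38), the source of positions, exon lengths and gene types. The symbols are those of the table. For 1289 IDs the annotation has another symbol, and 5 listed genes that the table gives under an older symbol (Ifit3b, Acod1, Adgre1, Adgre4 and Jchain) were found by ID. The IDs that the table pairs with Gbp5, Gbp6 and Yam1 carry the names Gbp2b, Gm43302 and Gm42418 in the annotation, so their identity is less sure. Immunoglobulin and T cell receptor constant genes are not among the rows, so B, plasma and T cells were followed by other markers.

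Counts were scaled to CPM with TMM factors from edgeR 4.0.16 in R 4.3.3. Totals were 16957371 counts for C57BL/6 and 15986392 for Ch25h-/-, and the TMM factors were 1.01 and 0.991. A gene was measured when its mean over both libraries was at least 1 CPM. The ratio is Ch25h-/- over C57BL/6 without a prior count. A count of 0 would be set to a preset floor of 3 counts, equal to 0.175 CPM in the C57BL/6 library and 0.189 CPM in the Ch25h-/- library. No measured gene had 0 counts in either library. Exact 95% intervals of the ratio are Clopper-Pearson intervals of one library's share of both counts, computed with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. They cover counting error only, without variation between mice, sorts or library preparations, and reads without molecular identifiers are not independent molecules. The median size of the interval to each side was 0.72 on the log2 scale for genes under 5 CPM and 0.09 for genes from 50 CPM.

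Genes were called higher or lower when the log2 ratio was at least 1 in size and the whole interval lay on 1 side of 0. No p-value was computed, because each genotype has 1 library. For 36 gene lists (pathways and cell type markers), the median log2 ratio of the measured genes was given its percentile among 10000 random lists of the same size. The random lists were drawn, with replacement, from measured genes outside the list in the same of 20 bins of mean CPM. A median was counted as outside the random lists under percentile 2.5 or over 97.5, for lists with at least 3 measured genes. Intervals of medians come from 500 Poisson resamplings of the counts. A percentile describes these 2 libraries, not the genotypes.

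The lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Ch25h, the 12 largest and 12 smallest log2 ratios among called genes with a mean of at least 10 CPM (leaving out provisional symbols), the 4 members of each list with the largest log2 ratio in size and its most abundant member, and the 5 most abundant genes. A few genes that the rule takes are not reported. Genes named beyond this rule were chosen after their values were seen. They are further members of the fixed lists, given for context. A further 3 lists, used only in the closing section, were written after the first results.

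The same steps were tested on counts simulated for all listed genes from the means and depths of these 2 libraries. Of the simulated genes, 11953 were measured. Of 96 measured genes changed 4-fold, 96 were called in the right direction. Of 99 changed 1.5-fold, 3 were called. Of 11758 unchanged genes, 22 were called, and 95.6% of intervals held the true ratio. The simulated counts hold counting error only, without variation between mice, sorts or library preparations. These values therefore check the calculation and are not error rates for the comparison of the genotypes.

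Alternatives were DESeq2 1.42.0 size factors, total counts, upper quartile scaling, scaling and totals without immunoglobulin, T cell receptor, haemoglobin, mitochondrial and S100a8/S100a9 genes, a filter at 5 CPM, no filter beyond 1 count, a prior count of 2, and an interval wholly beyond 2-fold. Figures were drawn with matplotlib 3.10.9.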

Results

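RNA sequencing was performed on CD11b-positive, Ly6G-negative, Ly6C-low cells sorted from mouse spleen 3 days after intravenous infection with 100000 *Listeria monocytogenes*, about 100000 cells per sort. The labels call these cells resident splenic macrophages. The design held 2 libraries, 1 from C57BL/6 mice and 1 from Ch25h-/- mice, which lack the enzyme that converts cholesterol to 25-hydroxycholesterol. The C57BL/6 library held 16957371 gene counts and the Ch25h-/- library 15986392. At least 1 count was seen for 15410 genes in the C57BL/6 library and for 15579 in the Ch25h-/- library. With 1 library per genotype there is no replicate check, so values below are ratios of these 2 libraries with exact 95% intervals that cover counting error only. A gene is called higher or lower when its scaled counts differ by at least 2-fold and its interval excludes a ratio of 1.

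The comparison asks how the transcriptome of these cells differs when Ch25h is missing. The targeted gene itself (Ch25h, ENSMUSG00000050370, a single-exon gene on the minus strand at GRCm38 chromosome 19, 34473778 to 34475164) had 3 counts in the C57BL/6 library, with an exact Poisson interval of 0.619 to 8.77 counts. It had 0 counts in the Ch25h-/- library, with an upper limit of 3.69 counts on the same interval. The preset floor of 3 counts equals 0.189 CPM (the TMM-scaled count relative to library size) in that library. Both values lie at or under that floor, so no fold is given, and the genotype labels are not decided by this gene at this depth.

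Of 11972 measured genes, 691 were lower and 248 were higher in the Ch25h-/- library. Among the 10077 genes with a mean of at least 5 CPM, 347 were lower and 120 higher. Among called genes with a mean of at least 10 CPM and no provisional symbol, the metallothionein gene Mt2 had the steepest decrease. The inducible heat shock genes Hspa1b and Hspa1a came next. Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) had 52.1 CPM in the C57BL/6 library and 3.22 CPM in the Ch25h-/- library, a log2 ratio of -4.02 (95% interval -4.45 to -3.61), and Mt1 stood at -2.73. Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) went from 279 to 19.8 CPM, a log2 ratio of -3.82 (-3.99 to -3.65). Its near-identical neighbour Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) went from 172 to 14.6 CPM (-3.56), and how reads were divided between these copies is not known. Ptgs2, the gene of cyclooxygenase-2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), was 6.36-fold lower, at 232 against 36.4 CPM (log2 ratio -2.67, interval -2.80 to -2.54).

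Ikzf4 (-3.13), Sphk1 (-2.93), the arginine transporter gene Slc7a2 (-2.83), the Notch ligand gene Dll4 (79.1 against 11.2 CPM, -2.82), Plat (-2.69), Mylk (-2.67) and Eno2 (-2.62) completed the 12 smallest log2 ratios. Annotated genes on the opposite strand overlap Mt2, Hspa1a, Ikzf4, Sphk1, Slc7a2, Dll4 and Mylk, and the labels do not say whether counting used strand.

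The 12 largest log2 ratios were smaller in size, between 1.36 and 1.90. They included 3 genes of natural killer (NK) cell receptors. Ncr1 (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164) had 156 CPM in the C57BL/6 library and 429 CPM in the Ch25h-/- library, a log2 ratio of 1.46 (95% interval 1.39 to 1.52). Klrc2 went from 47.0 to 138 CPM (1.55) and Klra3 from 19.5 to 57.2 CPM (1.56); both belong to families of similar genes, so their single values are uncertain. The T cell and NK cell costimulator gene Cd28 had 29.9 and 81.7 CPM (1.45). Fam19a3 (1.90), Chil1 (1.84), the neighbouring similar genes Khdc1b (1.82) and Khdc1a (1.77), Gpx8 (1.59), F2rl2 (1.36) and the cell cycle genes E2f7 (1.49) and Hells (1.43) made up the rest. Fam19a3, Gpx8, E2f7 and F2rl2 overlap other annotated genes.

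**Figure D1:**
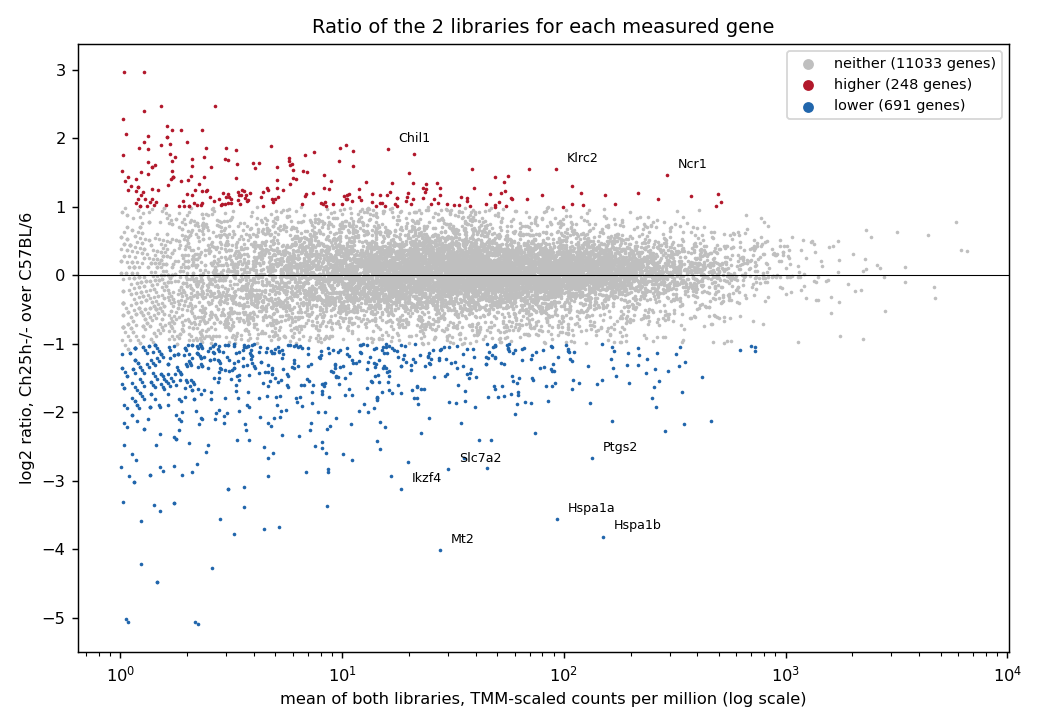
Each point is 1 of 11972 measured genes, with the mean CPM of both libraries on a log axis and the log2 ratio of Ch25h-/- over C57BL/6 on the vertical axis. Blue points are the 691 genes called lower and red points the 248 called higher, and lower calls reach further from 0.

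**Figure D2:**
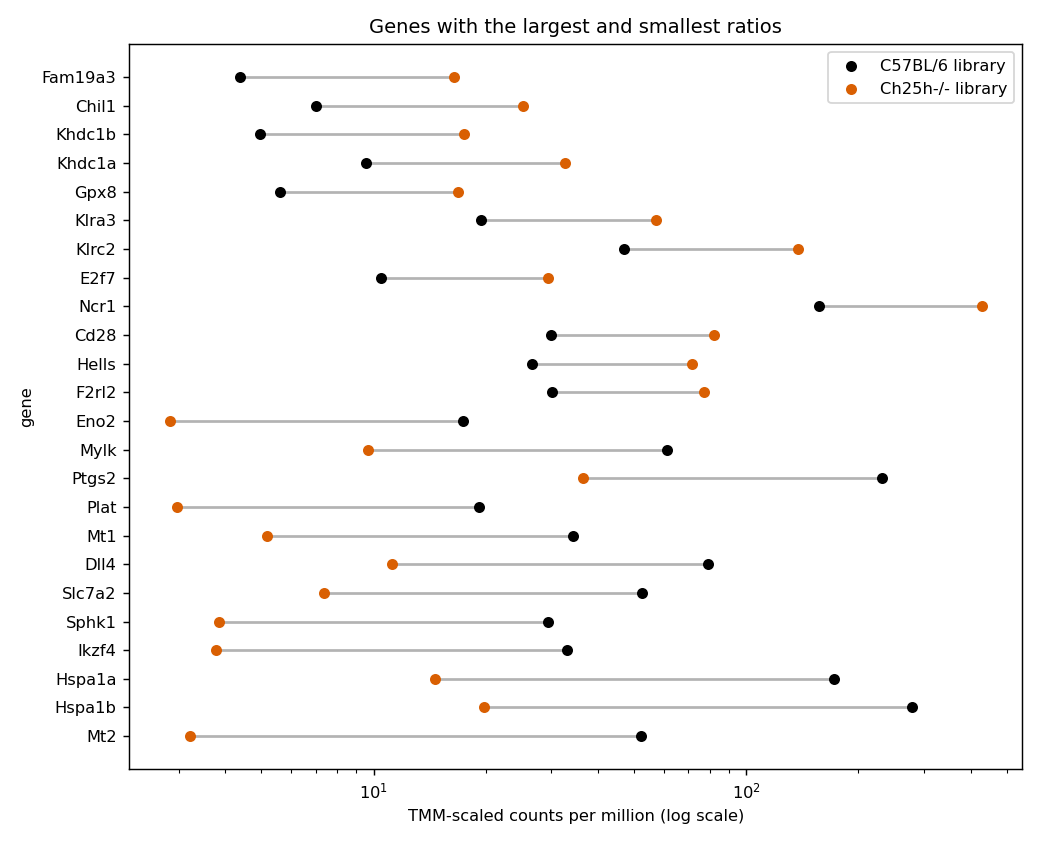
CPM in the C57BL/6 library (black) and in the Ch25h-/- library (orange), on a log axis, for the 12 genes with the smallest and the 12 with the largest log2 ratios among called genes with a mean of at least 10 CPM. Mt2, at the bottom, went from 52.1 to 3.22 CPM.

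Cytotoxic lymphocyte genes were abundant in both libraries and higher in the Ch25h-/- library. Gzmb was among the 5 most abundant genes, at 4356 CPM in the C57BL/6 library and 7429 CPM in the Ch25h-/- library (log2 ratio 0.77, interval 0.76 to 0.78). Gzma (0.58), Prf1 (0.55), Il2rb (0.65), Ifng (0.49), Tbx21 (0.84) and Eomes (0.58) moved the same way without reaching 2-fold. Klrd1 (1.04), Klre1 (1.17) and Xcl1 (1.20) passed the 2-fold rule together with Ncr1. All 16 genes of the NK cell and cytotoxic lymphocyte list had a log2 ratio above 0, and their median of 0.76 (interval 0.73 to 0.79) exceeded all 10000 random lists matched on expression. Gzma, Gzmb and Prf1 together took 0.994% of counts in the C57BL/6 library (exact binomial interval 0.989 to 0.998%) and 1.55% in the Ch25h-/- library (1.54 to 1.55%).

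Proliferation genes were higher as well. All 28 cell cycle genes had a log2 ratio above 0, with a median of 0.79 (interval 0.71 to 0.82), also above all 10000 random lists. Top2a went from 330 to 692 CPM (1.07), Mki67 from 590 to 1011 CPM (0.78), and Ccne2 (1.18), Ccna2 (1.17), Kif11 (1.04) and Rrm2 (66.3 against 133 CPM) were called higher.

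Antigen presentation genes moved the other way. All 15 genes of the MHC class II list had a log2 ratio under 0, with a median log2 ratio of -0.93 (interval -0.95 to -0.91), below all random lists. The costimulator genes Cd80 (88.6 against 26.5 CPM, -1.74) and Cd86 (166 against 52.2 CPM, -1.66), H2-Eb2 (-1.36), Lgmn (-1.35), H2-Aa (-1.10) and H2-Eb1 (-1.10) were called lower. Cd74, the most abundant of the list, had 2944 CPM in the C57BL/6 library and 1541 CPM in the Ch25h-/- library (-0.93). The MHC class I list stayed near 0, with a median of -0.09 at percentile 5.19 of the random lists; H2-K1 stood at -0.17, H2-Q4 at -0.34, H2-Q6 at -0.32, Psme2 at -0.33 and Erap1 at 0.25. Reads of the similar H2-Q genes can be divided between copies in ways not known here.

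Markers of dendritic cells and tissue macrophages were lower alongside the MHC class II genes. The conventional dendritic cell list had a median log2 ratio of -1.08 (interval -1.39 to -0.87), with 10 of 17 genes called lower. Fscn1 fell from 746 to 171 CPM (-2.13), Ccr7 from 413 to 109 CPM (-1.93), Ccl22 from 123 to 25.1 CPM (-2.30), Flt3 from 134 to 43.5 CPM (-1.62), and Esam (-2.66), Batf3 (-2.14) and Irf4 (-1.83) were also lower. Irf8, the most abundant gene of that list, stood at 0.49. Red pulp macrophage markers had a median of -0.72 (Trf -2.06, C1qa -1.40, Cd163 -1.33, Spic -1.17, Sirpa -0.71), and marginal zone and metallophilic macrophage markers one of -0.87 (Marco -1.56, Siglec1 -1.08, Tmem26 -0.87, Cd5l -0.48). The Ly6C-low monocyte list, the closest to the sorting gate, had a median of -0.33 at percentile 0.07. Within it Fcgr4 (-1.13) was called lower, and Ear2 (-0.76), Cd36 (-0.67), Cx3cr1 (0.62) and Itgal (0.41) did not reach 2-fold.

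Inflammatory cytokine and chemokine genes were lower alongside these markers, with 15 of 27 called lower and none called higher. Their median log2 ratio was -1.13 (interval -1.20 to -1.01), below all random lists. Il1b went from 427 to 162 CPM (-1.40), Il1rn from 373 to 144 CPM (-1.38), Cxcl2 from 112 to 43.7 CPM (-1.36), Tnf from 77.5 to 36.0 CPM (-1.11), Il6 from 21.9 to 8.52 CPM (-1.36) and Il12b from 26.2 to 10.4 CPM (-1.33). Cxcl1 (-3.71), Ccl24 (-2.93) and Ccl2 (-1.91) fell further from lower levels. Ccl5, the most abundant gene of the list, stood at 0.48, and Il10 at 0.52. NF-kB response genes had a median of -0.63, with Ptgs2, Cd83 (-1.20), Ier3 (-1.19) and Cd40 (-1.12) called lower and Tnfaip3 at 1503 against 761 CPM (-0.98). Alternative activation genes had a median of -1.36 (interval -1.63 to -0.68, and -0.67 over the 9 genes left by a filter at 5 CPM). Mrc1 (25.4 against 4.36 CPM, -2.54), Ccl22, Retnla (-2.25) and Arg1 (34.5 against 9.41 CPM, -1.88) were lowest. Chil4 (1.57) was called higher, and Chil3, the most abundant, was at 0.63. The lists overlap, since Ccl22 is on this list, the cytokine list and the conventional dendritic cell list.

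**Figure D3:**
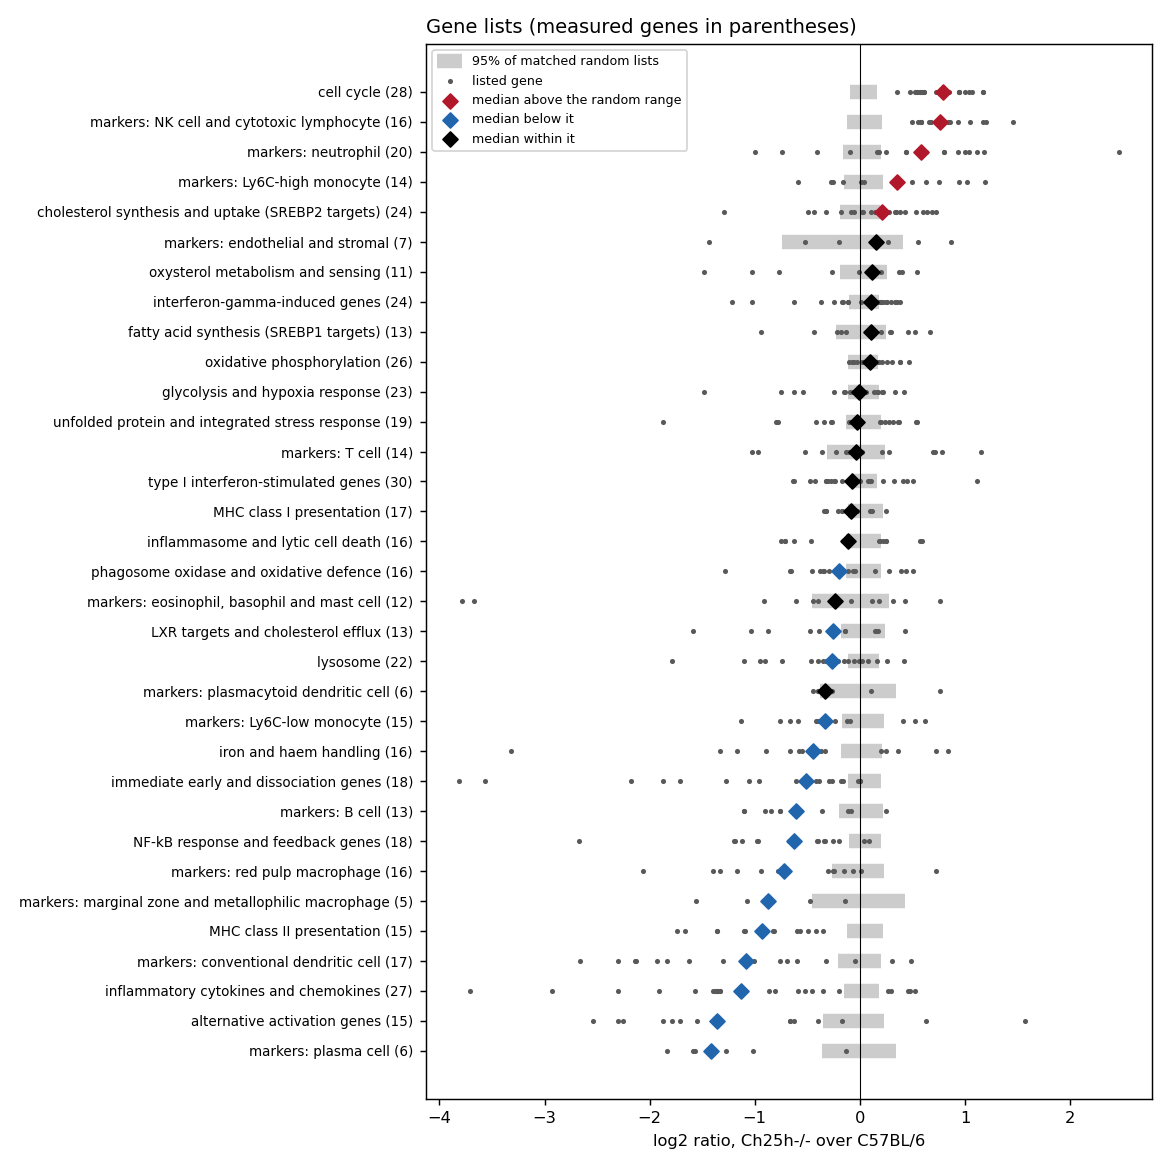
Log2 ratio of Ch25h-/- over C57BL/6 for each measured gene (grey points) of the 33 gene lists with at least 3 measured genes, with the list median (diamond) and the central 95% of medians of matched random lists (grey bar). Medians run from -1.42 for plasma cell markers to 0.79 for cell cycle genes.

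Sterol genes were examined because 25-hydroxycholesterol restrains SREBP2 and activates LXR. The cholesterol synthesis list had a median log2 ratio of 0.21 (interval 0.10 to 0.30) at percentile 98.5 (93.97 with a filter at 5 CPM, inside the random range), with Hmgcs1 (34.1 against 56.4 CPM, 0.73), Sqle (0.69) and Idi1 (0.64) highest, Srebf2 at -0.09, and Pmvk lower (76.3 against 31.1 CPM, -1.30). Fatty acid synthesis genes had a median of 0.10 at percentile 76.0; the most abundant, Scd1, went from 452 to 235 CPM (-0.94), and Fads1 (0.67), Elovl6 (0.53) and Acss2 (0.46) leaned higher. LXR targets had a median of -0.25 at percentile 0.57, with Apoe (211 against 70.3 CPM, -1.59), Pltp (-1.03) and Abca1 (181 against 99.2 CPM, -0.87) lowest, Cd5l at -0.48 and Nr1h2 at -0.29. These LXR genes moved in the direction of the macrophage markers, whose median was -0.72 for red pulp macrophages. Of the 13 measured genes of the LXR list, 4 lay above 0. The lists also overlap, since Mertk is a red pulp macrophage marker and Cd5l and Nr1h3 are marginal zone and metallophilic macrophage markers. The receptor gene Gpr183 (58.8 against 21.1 CPM, -1.48) and the oxysterol enzyme gene Hsd3b7 (-1.03) were called lower within an oxysterol list whose median was 0.11, where Cyp27a1 stood at -0.77, Sult2b1 at 0.55 and Npc2 at -0.27.

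Interferon-stimulated genes differed little. The type I interferon list had a median log2 ratio of -0.07 at percentile 3.35, with Oas2 at -0.64, Oasl2 at -0.63, Usp18 at 0.51 and Ifi44 higher (43.1 against 93.2 CPM, 1.11). The interferon-gamma list had a median of 0.10 at percentile 81.7. In it, Cd274 (936 against 458 CPM, -1.03) and Ido1 (5.43 against 2.34 CPM, -1.22) were lower, Nos2 stood at -0.62, and Cxcl10 was at 0.38. Inflammasome genes had a median of -0.11 at percentile 3.80, with Nlrc4 (-0.75), Nlrp3 (-0.72), Ninj1 (-0.71) and Nlrp1b (-0.63) lowest and Casp8 at 0.25.

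Stress-associated genes split. Of 18 immediate early and dissociation genes, 7 were lower, including Fosb (571 against 126 CPM, -2.18), Atf3 (97.1 against 26.4 CPM, -1.88), Dusp1 (-1.71), Fos (-1.27) and Zfp36 (982 against 472 CPM, -1.06), for a median of -0.51 below all random lists. Egr1, at 91.6 and 91.7 CPM, and Hspa8, at 658 and 651 CPM, were level. The unfolded protein response list had a median of -0.03 (Atf3 -1.88, Trib3 -0.80, Herpud1 -0.78, Dnajc3 0.54, Hspa5 -0.10).

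Metabolic and organelle lists went both ways. Glycolysis genes had a median log2 ratio of -0.01, with Pfkfb3 called lower (617 against 221 CPM, -1.48), Vegfa at -0.75, Hk2 at -0.63, Pfkfb4 at -0.54 and Pkm at 0.04. Oxidative phosphorylation genes had a median of 0.09 at percentile 79.3, and their largest ratios were Cycs (0.47), Ndufs8 (0.38), Sdhb (0.38) and Atp5c1 (0.31), with Atp5b at 0.18. Lysosome genes (median -0.26, percentile 0.01) included Cd63 (-1.79), Ctsl (-1.10), Gla (-0.95), Ctsz (-0.90) and, on the other side, Ctsd (0.42). Phagosome oxidase and oxidative defence genes had a median of -0.20 at percentile 0.45, with Slc7a11 called lower (-1.28), Hmox1 and Sod2 at -0.66, Prdx1 at 0.50 and Rac2 at 0.27. Iron and haem genes had a median of -0.44, with Hamp (54 against 5 counts, -3.32), Cd163 and Spic lower and Fth1 at -0.89. Cd163 and Spic are also on the list of red pulp macrophage markers.

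Markers of further cell types also differed. Neutrophil markers were higher, with a median log2 ratio of 0.58 above all random lists and 5 of 20 genes called higher. They were Ngp (322 against 646 CPM), Ltf (168 against 364 CPM, 1.12), Mmp9 (1.18), Camp (1.04) and Ly6g (8 against 41 counts, 2.47). Ly6C-high monocyte markers had a median of 0.35, with Ccr2 (304 against 691 CPM, 1.19) and Vcan (1.02) higher, Cd177 at 0.94 and Ly6c2 at 0.75. B cell markers were lower (median -0.61; Ebf1 -1.10, Fcrla -1.10, Bank1 -0.85, Cd22 -0.61), as were plasma cell markers (median -1.42; Irf4 -1.83, Sdc1 -1.59, Derl3 -1.56, Mzb1 -1.28, Prdm1 -0.14). Irf4 is also on the conventional dendritic cell list, and Prdm1 was the most abundant measured plasma cell marker. T cell markers had a median of -0.04, with Ms4a4b higher (233 against 517 CPM, 1.15), Il7r lower (-1.03), Tcf7 at -0.97, Lck at 0.78 and Cd3e at 6.49 and 7.51 CPM.

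Among eosinophil, basophil and mast cell markers (median -0.24 at percentile 15.96; -0.53 at percentile 1.03 over the 6 genes left by a filter at 5 CPM), Epx (-3.78) and Prg2 (-3.67) were lower, Il5ra stood at -0.91, Cd200r3 at 0.76 and Kit at -0.60. Plasmacytoid dendritic cell markers had a median of -0.33 at percentile 3.59, which became 1.93 with a filter at 5 CPM and 29.4 with no filter beyond 1 count (Ccr9 0.76, Spib -0.45, Tcf4 -0.40, Pacsin1 -0.40, Runx2 0.11). Endothelial and stromal markers had one of 0.15 (Stab2 -1.44, Col1a2 0.87, Acta2 0.55, Cxcl13 -0.52, Pecam1 0.15). Only Car2 and Tfrc of the erythroid list (both 0.84) and Itga2b of the megakaryocyte list (-0.64) were measured. Xist had 1192 CPM in the C57BL/6 library and 1510 CPM in the Ch25h-/- library, with 0 counts of 4 Y-linked genes in both. The other most abundant genes were mt-Co1 (0.35), Actb (0.36), Yam1 (-0.34) and H2-K1.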

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

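The alternatives were chosen before the data were examined. Against 248 genes higher and 691 lower, a filter at 5 CPM left 120 higher and 347 lower, and an interval wholly beyond 2-fold left 67 higher and 318 lower, all of them among the genes called under the chosen settings. No filter beyond 1 count gave 435 higher, and 1031 lower, which include all genes called under the chosen settings. A stricter interval can only remove calls, and the looser filter only added them. The filter at 5 CPM kept 10077 of 11972 measured genes, but 120 of 248 higher and 347 of 691 lower calls. Many calls under the chosen settings therefore lay among the 1895 measured genes under 5 CPM, where counting intervals are wide. The other 5 alternatives gave 222 to 252 higher and 647 to 722 lower.

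Scalings moved all log2 ratios by at most 0.03 in size, and neither the medians of the 20 lists outside the random lists nor the named genes called higher or lower changed sign under any alternative. No called gene could have been reversed, since these shifts are small, filters leave ratios unchanged and a prior count only shrinks them. Scalings also shift a list and its random lists alike, so only the filters, the prior count and the omitted genes could move a percentile much. Of the 20 lists outside the random lists, 19 stayed outside under all 7 alternatives tried on them, and the cholesterol synthesis list did not. Its percentile of 98.5 became 93.97 with the 5 CPM filter, which leaves 21 of its 24 genes, and 95.8 with no filter beyond 1 count, which adds 1 gene. The plasmacytoid dendritic cell list moved from percentile 3.59 to 1.93 with the 5 CPM filter, which leaves 5 of its 6 genes, and to 29.4 with no filter beyond 1 count, which gives 8 genes (median -0.33 to -0.08). The eosinophil, basophil and mast cell list moved from percentile 15.96 to 1.03 with the 5 CPM filter, which leaves 6 of its 12 genes (median -0.24 to -0.53). Of 231 list medians recomputed, 223 stayed within their counting interval. The largest move was that of the alternative activation list, from -1.36 to -0.67 with the 5 CPM filter, which leaves 9 of its 15 genes. The Ch25h level in the C57BL/6 library stayed within its counting interval under each scaling. With an interval of 0.619 to 8.77 counts, no scaling could have moved it out, so this is no check of the gene. A prior count gives Ch25h no usable ratio because both libraries are at or under the floor of 3 counts. Calls among genes under 5 CPM are the least sure, since the median size of the interval there is 0.72 to each side.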

Other observations

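The tests of scaling, of fewer myeloid cells alone, of the cytokine genes, of reads shared by Hspa1a and Hspa1b, of the 4 stress genes against the myeloid markers, and of the window around Ch25h, were chosen after the results were seen. The tests on second lists of NK cell, of dendritic cell and macrophage, and of heat shock genes were written before those genes were looked at, except that the decrease of Slco5a1 had been seen.

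NK cell genes were higher while dendritic cell, macrophage and MHC class II genes were lower in the Ch25h-/- library. One scaling error of a library would shift both alike, and the medians of NK cell and dendritic cell markers differ by 1.84 on the log2 scale. A lower share of dendritic cells and macrophages alone would raise the markers of all other cells alike, yet NK cell markers exceed B cell markers by 1.37, with quartiles of 0.59 to 0.96 against -0.85 to -0.36. A larger share of NK cells in the sorted population may explain the higher NK cell genes. It does not cover the neutrophil and Ly6C-high monocyte markers (medians 0.58 and 0.35), which were higher too although the gate was set against Ly6G-positive and Ly6C-high cells. In a second list of 17 NK cell genes, 100% had a log2 ratio above 0 (median 0.67), among them Samd3 (1.13), Klrc1 (0.95), Itga2 (0.91) and Klrk1 (0.70). The lowest of that list were Cd160 (0.05, interval -0.26 to 0.35, which includes 0), S1pr5 (0.24) and Gzmc (0.25), so its genes were not raised evenly. Serpinb9, the most abundant, had 864 and 1267 CPM (0.55). Cytotoxic T cells express part of both lists and stay open as a source, although a gate on CD11b removes most T cells. T cell markers had a median of -0.04, with Cd3e at 6.49 and 7.51 CPM, but Ms4a4b (1.15) and Cd28 (1.45) were called higher and Lck stood at 0.78. The gate on CD11b, Ly6G and Ly6C was not set against a marker named for NK cells. Which part of the NK cells it kept in each sort is not known. A smaller share of dendritic cells and macrophages was left undecided by its second list. Its 21 genes had a median of -0.46, below all 10000 random lists, but 76.2% of them lay under 0, short of the 80% set beforehand, with Slco5a1 (-1.57) and Cst3 (362 against 165 CPM, -1.14) called lower and Lyz2 at 0.60 and Naaa at 0.62. A response of each cell type to the missing gene remains open and untested, and with 1 library per genotype a difference between sorts remains open too.

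Inflammatory cytokine and chemokine genes were lower in the Ch25h-/- library, as were dendritic cell and macrophage markers. The 26 cytokine genes that are in no marker list had a median log2 ratio of -1.12, against -0.77 for 38 dendritic cell and macrophage markers. That median lies at percentile 6.10 among medians of 26 genes drawn from these markers (central 95%, -1.21 to -0.45). This comparison leaves open whether the same loss of dendritic cell and macrophage RNA explains the decrease, since both medians had been seen and a lost subset of cells can hold such transcripts. Lower expression per cell in the Ch25h-/- library was not tested, since bulk counts do not separate it from cell numbers.

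Hspa1a, Hspa1b, Mt1 and Mt2 were among the genes with the steepest decreases. A different division of reads between Hspa1a and Hspa1b does not account for the decrease of these 2 genes, since their summed counts had a log2 ratio of -3.71 (interval -3.84 to -3.59). A weaker heat shock response from handling of the cells would lower other targets of heat shock factors as well. The 13 measured genes of a second list had a median of 0.11, with quartiles of -0.06 and 0.27. A handling difference of another kind stays open, since the immediate early and dissociation list had a median of -0.51, with Fosb (-2.18), Atf3 (-1.88), Dusp1 (-1.71), Fos (-1.27) and Zfp36 (-1.06) lower. Loss of dendritic cell and macrophage RNA stays open. The median of the 4 genes, -3.69, lies under the markers' lower quartile of -1.38, but they were picked for their steep decrease, and a lost subset can hold such transcripts. Loss of a rare cell type that holds these transcripts, metal-dependent regulation of Mt1 and Mt2, and an effect of the genotype were not tested.

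Around the targeted gene, 105 measured genes lie within 10 Mb on chromosome 19. Of these, 8 were lower and 5 higher, 12.4% in all, against 7.84% of all measured genes, and their median log2 ratio was -0.06. Genes named above lie in this window, among them the cell cycle genes Kif11 and Hells, called higher, and Cd274, called lower. Across genes, exon length and the log2 ratio had a Spearman rho of 0.00082. Median exon length was 3338.5 bases for genes called higher, 4038 for genes called lower and 4472 for the other measured genes. Mitochondrial genes took 1.18% of counts in the C57BL/6 library (exact binomial interval 1.17 to 1.18%) and 1.49% in the Ch25h-/- library (1.488 to 1.499%).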
